A study of Caenorhabditis elegans with 2 samples.

How the data were processed

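Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole L4 larvae, the last larval stage, of a Caenorhabditis elegans strain that carries an inserted eGFP-tagged fos-1 gene, in 2 biological replicates of mixed sex, per the labels. FOS-1 is the worm relative of the mammalian Fos proteins, which are basic leucine zipper (bZIP) transcription factors. Both samples formed 1 group, so no condition was compared with another. Each number is therefore a property of the peak lists, tested against other regions or genes of the same genome.

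The deposited peak lists, on builds ce10 and ce11, were made by the authors, and the peak caller, the aligner and the threshold of the irreproducible discovery rate (IDR, a measure of how well replicates rank the same regions) are not given in the sources used here. Per the file list deposited with each sample, each replicate list holds peaks and background called on 1 alignment of that replicate with a control alignment, the same for both replicates. The pooled list, also of peaks and background, comes from both replicate alignments with that control. The IDR-thresholded set comes from the pooled list and both replicate lists. The signal of a peak is the authors' peak caller's own value, deposited without its scale, and was used to describe and rank peaks within a list. Its medians were also compared between sets of peaks of the pooled list by permutation and bootstrap over peaks, and its ranks between the replicate lists by Spearman's correlation, and peaks are not independent replicates in either. The −log10 q-value of a peak is also the authors' deposited value. Read counts were not used here, so the depth per sample is unknown. The precision given is that of the number of peaks or genes, as exact Clopper-Pearson 95% intervals that cover counting error only, and neighbouring peaks are not independent of each other.

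Coordinates, genes and sequences were taken from ce11, the build of the reference genome, with Ensembl annotation release 115. Lists on ce10 were used for counts, chromosome shares and replicate comparisons only, and the X share on ce10 was set against the ce11 chromosome lengths. Summits were assigned to a promoter when they lay from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding gene. The place of a summit (exon, intron, untranslated region, intergenic) was read from the same annotation. The 1763 lowest-ranked regions of the pooled list served as the background for promoters. The AP-1 motif, TGASTCA with S for C or G, was searched on both strands within 100 bp to each side of each summit and in windows of the same width centred 1000 bp to each side. Its odds ratio was ranked among 64 heptamers of the same palindromic form. Replicate summits matched when they lay within 200 bp. For comparison, summits were placed at random, uniformly within their chromosomes.

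Shares were compared with 2-sided Fisher's exact tests and the X share with a 2-sided exact binomial test against the length of the nuclear chromosomes. Genes with a promoter summit were counted in 23 gene lists fixed beforehand, against all other protein-coding genes or, for the tRNA and snoRNA lists, all genes with a position, with Benjamini-Hochberg adjustment over the 23 lists. A list was called at an adjusted p under 0.05. A single symbol of the bZIP list and a single symbol of the stress list had no match in the annotation and were left out. The pattern that defined the ribosomal protein list missed 2 symbols with a capital letter, and the list with both was run as an alternative added after seeing the data. The gene lists, tests and most alternatives were fixed before the data were examined. The named genes follow a rule fixed then as well: fos-1, unc-119, zmp-1, cdh-3, him-4 and egl-43; the nearest protein-coding gene of the 20 IDR peaks with the highest signal; and up to 4 members per list with the highest-signal promoter peak. Any other gene named in the text was chosen after its values were seen.

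The alternatives were each replicate list alone (its highest-signal 248 regions), the 124 peaks of the set with the highest signal, other promoter and motif windows, other backgrounds, other matching distances and build ce10. Nuclear chromosomes only, removal of X-linked peaks, ranking of motifs by p and another comparison for the RNA gene lists were added after seeing the data. Sequence hexamers, the dosage compensation motif and the stretch around fos-1 were also examined after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used with random seed 20, 100000 resamples for permutation tests and 10000 for bootstrap intervals. Tested on simulated data, the motif search recovered 55 of 55 expected windows after 50 motifs were planted among 248, although the planted motif ranked 2 by odds ratio and 1 by p. The expected windows were set with the same pattern and the motifs were planted inside the windows, so that recovery checks the counting only. A list with 10 of 60 members given a promoter summit was called in 50 of 50 simulations, and 3 of 1000 null lists were called.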

Results

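The data are ChIP-seq peak lists for eGFP-tagged FOS-1 in whole C. elegans L4 larvae, from 2 biological replicates of 1 group. The question they address is where in the genome tagged FOS-1 was found at this stage, and no other stage, strain or condition was compared. The main list is the authors' IDR-thresholded set of 248 peaks on build ce11, each 344 bp wide. These are exactly the 248 highest of the 3527 regions in the pooled list, and on build ce10 the set holds 205 peaks. The authors' signal ranged from 31.1 to 162 over the set, with a median of 38.1. The replicate 1 list holds 30000 regions and the replicate 2 list 29345, background included.

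The peaks of highest signal lay mostly outside genes, and 11 of the top 20 were on the X chromosome. The highest, at X 11094020 to 11094363, was intergenic with a signal of 162, and its nearest protein-coding 5' end was that of W02H3.3, 3994 bp away. The next, at X 1454451 to 1454794, had a signal of 132 and lay 755 bp upstream of cebp-1, which encodes a bZIP transcription factor. Among the other top peaks, rpl-3, rpl-20 and rpl-15 (ribosomal proteins), cox-5A (a subunit of cytochrome c oxidase), cdc-48.1 (an AAA ATPase that unfolds ubiquitinated proteins), wwp-1 (a ubiquitin ligase), nspc-17, fbxb-58 and Y17G9B.5 had the peak in their promoter. The peak upstream of rpl-3, at III 3867407 to 3867750, had a signal of 111. The remaining nearest genes were F20B6.9, F22H10.2, F19H6.5, ZK1248.17, K02D3.1, mom-1, pqn-41, xol-1, Y111B2A.12 and ZK899.6. The peak nearest xol-1, a sex determination gene that responds to X dosage, lay 4869 bp upstream. Of the 20 summits, 17 were intergenic and 3 intronic, and the lowest of the 20 signals was 76.3.

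Over the whole set, X held 55 of 248 peaks, 22.2% (95% interval 17.2 to 27.9), against 17.7% of the nuclear genome length, a difference that did not pass the exact binomial test (p = 0.0669). Chromosome II held 42 peaks, III 41, V 39, IV 38 and I 33. X-linked peaks were a larger share of the top 20 than of the other 228, of which 44 were on X (odds ratio 5.11, 95% interval 1.79 to 14.8, Fisher's exact p = 8.44e-04). That comparison was chosen after the values were seen. The median signal was 43.3 on X and 37.5 on the autosomes, a difference of 5.78 whose bootstrap 95% interval, −1.31 to 15.6, includes 0. The 14 X-linked peaks with a MEX consensus, a motif of dosage compensation sites, had a median of 74.5 and the other 41 a median of 36.4 (permutation p = 3.70e-04), a split made after the data were seen. The X share passed the test in each replicate list alone, at 22.6% in replicate 2 (exact binomial p = 0.0457) and 25% in replicate 1 (exact binomial p = 0.00349), and in the higher-signal 124 peaks of the set, at 27.4% (exact binomial p = 0.00653).

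**Figure D1:**
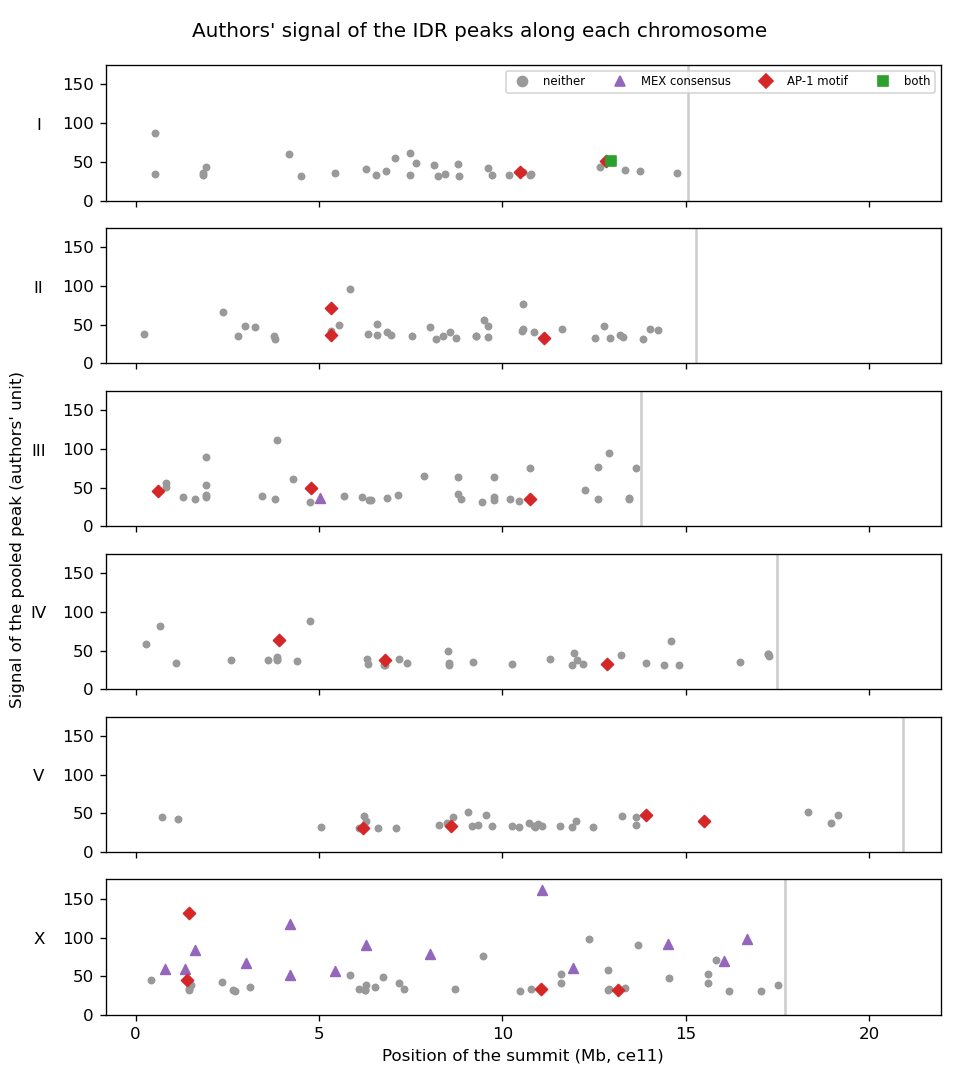
Authors' signal of the 248 IDR peaks (vertical axis) against the position of the summit in Mb on ce11 (horizontal axis), 1 panel per chromosome, with a grey line at the chromosome end. Diamonds are peaks with the AP-1 motif, triangles peaks with the MEX consensus at up to 2 mismatches, the square a peak with both and circles the rest; the highest signal, 162, is on X.

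The replicates shared part of their strongest regions. Of the 248 highest regions of replicate 1, 90 (36.3%, 95% interval 30.3 to 42.6) had a summit within 200 bp of one of the 248 highest of replicate 2, against a mean of 0.231 in 1000 random placements. These placements were uniform along each chromosome, so they do not separate FOS-1 signal from anything else both lists share, such as the control alignment. The peak near cebp-1 ranked 2 in replicate 1 and 17 in replicate 2, and the top 20 IDR peaks all ranked at or above 48 in replicate 1 and at or above 127 in replicate 2. Nearly all IDR summits were found somewhere in the long replicate lists, 244 in replicate 1 and 245 in replicate 2, where random placements gave means of 28.2 and 27.3. The IDR set was made from these lists, so that match is largely built in and is no measure of agreement between replicates. Across the 241 IDR peaks matched in both lists, Spearman's correlation of the signals was 0.235, and across 2364 matched pooled regions outside the set it was −0.198; peaks are not independent replicates. Both sets are defined by their place in the pooled ranking, which leaves out regions low in both replicates, so these values describe the sets and not the agreement of the libraries. The 18 regions of replicate 2 on mitochondrial DNA all lay within its top 248, and without them the share matched was 37.1%. Among the nuclear regions of replicate 2, the peak near cebp-1 ranked 2 and the top 20 IDR peaks all ranked at or above 110.

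**Figure D2:**
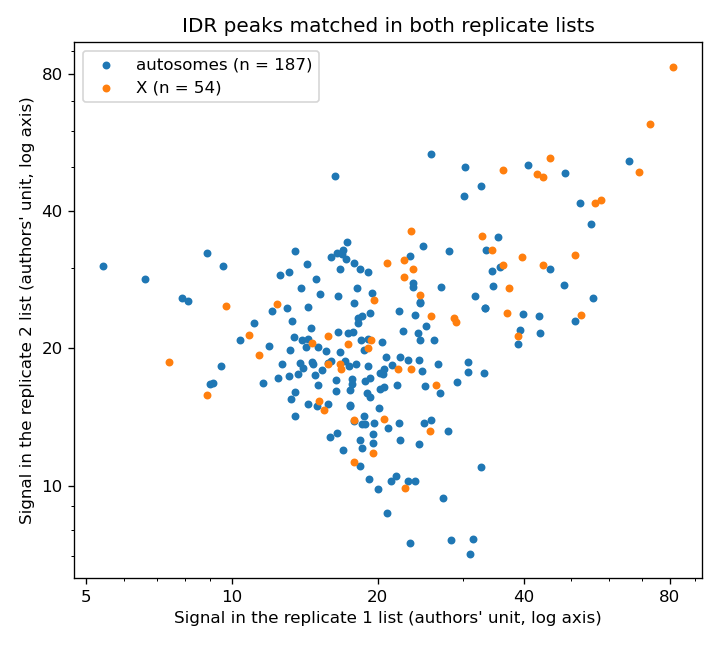
Signal of the 241 IDR peaks matched in both lists, replicate 1 on the horizontal and replicate 2 on the vertical axis, both logarithmic and in the authors' unit, with 1 point per peak coloured by X or autosome. The points scatter widely, with a Spearman correlation of 0.235.

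Peaks lay near promoters more often than weaker regions of the same pooled list. A promoter summit was found for 126 of 248 IDR peaks (50.8%, 95% interval 44.4 to 57.2) and for 626 of 1763 regions in the lower part of the list, by rank (35.5%, 95% interval 33.3 to 37.8). The odds ratio was 1.88 (95% interval 1.42 to 2.47, Fisher's exact p = 4.71e-06). It was lower in the replicate 2 list alone, at 1.45, and in the replicate 1 list alone, at 1.36. Intergenic summits made up 64.5% of the set and 44.6% of the lower-ranked part (adjusted p = 2.37e-08 over 6 kinds of place, Fisher's exact test). Coding exons held 4.03% against 15.6% (adjusted p = 1.64e-07, Fisher's exact test) and introns 20.2% against 31.4% (adjusted p = 4.22e-04, Fisher's exact test). Untranslated regions did not pass, with 19 peaks in 3' UTRs and 8 in 5' UTRs. The comparison by place was added after the data were seen.

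The AP-1 motif, the binding site of Fos and Jun proteins, was present at a minority of peaks but more often than beside them. It was found in 20 of 248 summit windows (8.06%, 95% interval 5.0 to 12.2) and in 5 of 496 flanking windows (1.01%, 95% interval 0.328 to 2.34). The odds ratio was 8.61 (95% interval 3.08 to 29.7, Fisher's exact p = 1.51e-06). It was 5.61 in the replicate 2 list alone, 3.13 in the replicate 1 list alone and 3.59 with the lower-ranked part of the pooled list in place of the flanks. The window at cebp-1 held 2 sites, 1 of them TGAGTCA at X 1454587 to 1454593. In introns of vhp-1, which encodes a MAP kinase phosphatase, the peak at II 5336904 to 5337247 (signal 71.3) and the peak at II 5332751 to 5333094 (signal 37) each held 1 site; this gene was chosen after its values were seen. The median distance from motif centre to summit was 56 bp, and 9 of the 20 motifs nearest a summit lay within 50 bp of it. The motif ranked 1 by odds ratio among the 64 heptamers of the same palindromic form only, with an adjusted p of 9.65e-05 (Fisher's exact test). Its rank was 5 in the replicate 2 list alone, 8 in the replicate 1 list alone and 7 in the higher-signal 124 peaks of the set. Down the pooled list its share was 5.16% at ranks 249 to 500 and 2.10% at ranks 2001 to 3527.

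**Figure D3:**
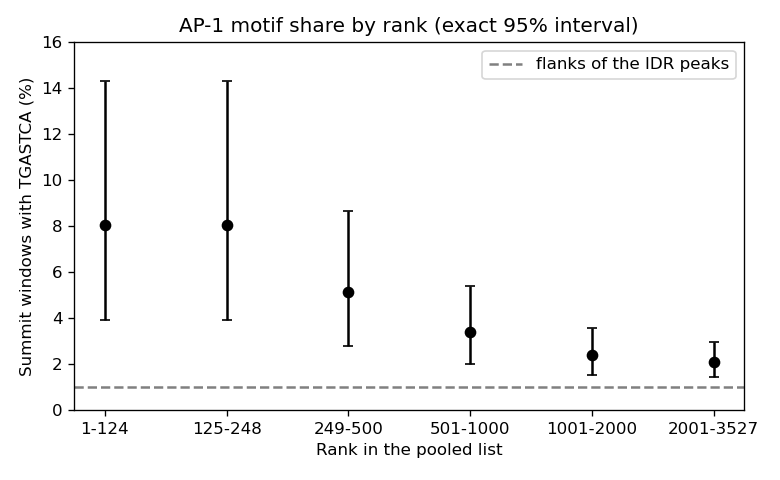
Percent of windows of 100 bp to each side of the summit with the AP-1 motif (vertical axis) by rank in the pooled list (horizontal axis), with exact 95% intervals as bars and the flank share of 1.01% as a dashed line. The share is 8.06% at ranks 1 to 124 and at ranks 125 to 248 and 2.10% at the end of the list.

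Of 19973 protein-coding genes, 161 had an IDR summit in the promoter, and genes of the ribosomal protein, snoRNA and stress response lists were more frequent among genes with a promoter summit. Of the ribosomal protein list, 8 of 76 members had a promoter summit (odds ratio 15.2, 95% interval 6.19 to 32.4, adjusted p = 2.04e-06, Fisher's exact test). The highest were rpl-3 at 111, rpl-20 at 88.6, rpl-15 at 81.5 and rpl-35 at 64.6 in signal. The list as fixed missed rpl-7A and rpl-36.A, and rpl-7A also had a promoter summit, at IV 4390514 to 4390857 (signal 36.2). With both added, after the data were seen, 9 of 78 members had one (adjusted p = 1.50e-07, Fisher's exact test). Counting only the nearest 5' end at any distance, 5 of the 76 were hit (odds ratio 6.21, adjusted p = 0.0332, Fisher's exact test). snoRNA genes, whose products guide modification of ribosomal RNA, had 16 of 346 members with a promoter summit (odds ratio 9.20, 95% interval 5.12 to 15.5, adjusted p = 3.22e-09, Fisher's exact test). They came from 13 peaks, of which 4 were also at ribosomal protein promoters, that of rpl-7A included, and the highest were K11H12.12 and K11H12.13 at the rpl-15 peak, C06A1.9 at 77.3 and T27A8.8 at 69.8. The replicate 2 list alone gave 7 members (odds ratio 4.78) and the replicate 1 list alone 17 (odds ratio 10.7), and against protein-coding genes, a comparison added after the data were seen, the odds ratio was 5.97. The stress response list had 3 of 30 members, the chaperone genes hsp-1 (42.5), hsp-60 (35.8) and hsp-3 (34.3) (odds ratio 13.9, 95% interval 2.67 to 45.9, adjusted p = 0.0136, Fisher's exact test). This list did not pass in the replicate 2 list alone (2 members, odds ratio 11.1, adjusted p = 0.0920, Fisher's exact test). It did not pass either in the replicate 1 list alone (1 member, odds ratio 5.26, adjusted p = 0.687, Fisher's exact test) or in the higher-signal 124 peaks (1 member, odds ratio 9.26, adjusted p = 0.491).

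The bZIP list had 2 of 27 members with a promoter summit, cebp-1 (132) and zip-2 (50.2), and did not pass after adjustment (odds ratio 9.96, adjusted p = 0.114, Fisher's exact test). It passed in the replicate 1 list alone (4 members, adjusted p = 2.12e-04, Fisher's exact test) and in the replicate 2 list alone (3 members, adjusted p = 0.00712). The matrix protease and inhibitor list had 2 of 50, nas-4 and tim-1 (adjusted p = 0.283, Fisher's exact test); tim-1 encodes a homolog of the circadian protein Timeless, not a protease or an inhibitor. Nuclear hormone receptors had 3 of 274 (nhr-119, nhr-68 and nhr-135), tRNA genes 2 of 612, cuticle collagens 1 of 174 (col-63), actin and actomyosin 1 of 29 (cap-2) and core histones 1 of 72 (his-37); none of these lists passed.

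No member of the other 13 lists had a promoter summit, over 503 listed memberships. These lists were anchor cell invasion (17 genes), spermatheca and ovulation (16), vulva and uterus development (20), basement membrane and matrix receptors (24), molting (19), MAP kinase signalling (25), C-type lectins (240) and the markers of intestine (25), epidermis (19), body wall muscle (20), pharynx (17), neurons (30) and germline (31). For anchor cell invasion a count of 0 allows a share of up to 19.5%, and for C-type lectins up to 1.53% (exact 95% intervals). Most of these lists are short, so a moderate excess was not detectable.

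**Figure D4:**
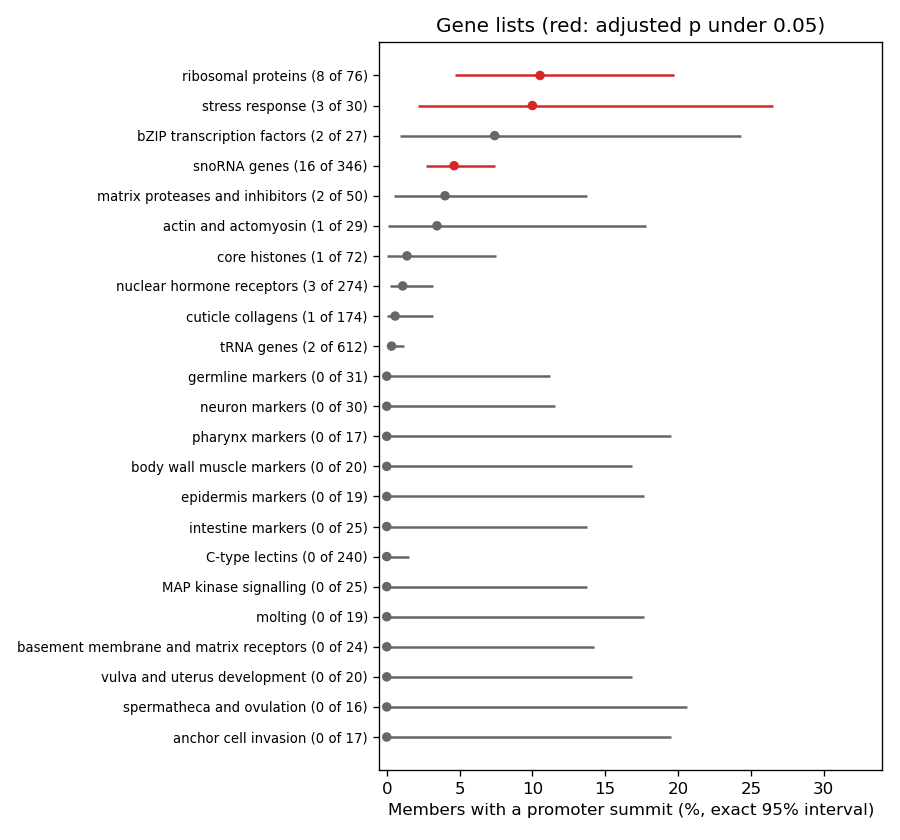
Percent of the members of each of the 23 gene lists with an IDR promoter summit (horizontal axis), with exact 95% intervals as bars and the counts in the row names; red marks an adjusted p under 0.05. Ribosomal proteins, stress response and snoRNA genes are the 3 in red.

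None of the genes followed for the known roles of fos-1 had an IDR peak within 20000 bp. fos-1 is required in the anchor cell for invasion through the basement membrane, and zmp-1 (a matrix metalloprotease), cdh-3 (a protocadherin), him-4 (hemicentin) and egl-43 (a zinc finger transcription factor) are studied with it there. From the density of the set, only 0.114 to 0.188 IDR peaks were expected around each of these 6 loci, unc-119 included, so a count of 0 carries little information. Weaker pooled regions within that distance numbered 8 for cdh-3 against 1.87 expected from the density of the pooled list, 2 for zmp-1 against 1.62, 3 for him-4 against 2.68 and 2 for egl-43 against 1.68, without a test. The best of them ranked 262 for egl-43, 403 for zmp-1, 523 for cdh-3 and 2081 for him-4. The pooled list includes background, with a median −log10 q of 0.131 over all its regions, so these regions need not be binding sites. Around fos-1 itself, at V 6003601 to 6016087, the nearest IDR summit lay 82749 bp away. The 20000 bp to each side of fos-1 held 2 regions of the replicate 1 list and 0 of the replicate 2 list, against 15.7 and 15.4 expected from the density of the lists. Around unc-119, the rescue marker gene of the strain's background, there were 10 and 18.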

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

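A signal appeared on mitochondrial DNA, which carries none of the nuclear genes compared. The replicate 2 list holds 18 regions on the mitochondrial genome of 13794 bp, above the 3 that a count of 0 allows, and the replicate 1 list holds 0. All 18 are among the 248 highest regions of replicate 2, with a best rank of 1 and a highest signal of 366, and neither the pooled list nor the IDR set has any. On build ce10 the replicate 2 list has 20 such regions. The 18 stayed among the 248 regions of the replicate 2 list used alone, where the promoter share was 44.4%. With nuclear chromosomes only it was 48.8%. No explanation was tested.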

How the results depend on the processing

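Of 85 recomputed values, 66 were counted as the same. They kept their direction and side of the threshold, moved within their error or, for counts and ranks, stayed within a fixed fold of the main value. Some of the 66 could not change by construction, so the tally overstates stability. A further 9 moved, 5 lost a call, 5 gained one, all for the X share, and 0 reversed. Gains of gene lists not called in the main analysis are outside this tally. The cause of a change was not tested unless it follows from the construction. The promoter share stayed past the test under every alternative run, from 36.3% with the narrow promoter window to 65.7% with the wide one, and so did the AP-1 share, from 3.23% to 10.1% with the narrower and the wider motif window, although its odds ratio was 3.13 in the replicate 1 list alone, 3.86 with the wider window and above the main value with the narrower one. The background of the promoter share moved with the window, to 21.8% for the narrow and 53.9% for the wide one. Its odds ratio, 1.88 in the main analysis, was 3.02 against uniform random positions. In the replicate 2 list alone it was 1.45 (Fisher's exact p = 0.00746), and in the replicate 1 list alone 1.36 (Fisher's exact p = 0.0289). The X share passed the exact binomial test where the main value did not in the replicate lists alone (22.6% to 25%), the higher-signal 124 peaks (27.4%), build ce10 (23.4%) and the nuclear regions of replicate 2 (24.2%, added after seeing the data). The rank of the AP-1 motif, 1 in the main analysis, was 5 to 8 in the replicate lists alone, 7 in the higher-signal 124 peaks, 6 with the narrower window and 5 against the lower-ranked part of the pooled list. Replicate overlap was 29.4% for the top 2N regions, 45.2% for the top N/2 and 29.0% for summits within 100 bp. The higher-signal set holds 124 peaks by construction. The number of gene lists called was 2 to 4, but the lists differed: ribosomal proteins passed in every alternative run (odds ratio 6.21 with nearest genes to 24.6 in the higher-signal 124 peaks) and snoRNA genes in every one that gave a value (4.23 in the nuclear regions of replicate 2 to 11.6 in the higher-signal 124 peaks), while the stress response list lost its call in each replicate list alone, in the nuclear regions of replicate 2, in the higher-signal 124 peaks and without X-linked peaks. The bZIP list, not called in the main analysis, passed in each replicate list alone, in the nuclear regions of replicate 2, in the higher-signal 124 peaks, with the wide promoter window and with nearest genes at any distance, and the matrix protease list passed against drawn low-ranked regions. With nearest genes at any distance the snoRNA list was not run, and no odds ratio could be had for the stress list against drawn low-ranked regions. Leaving out peaks near fos-1 and unc-119 removed 0 peaks and says nothing about stability. Depth is unknown, so its part in any of these differences stays open. No paired analysis was possible because there is 1 group.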

Other observations

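All hexamer values here, and the tests of a rise over the whole of X, of the limit on AP-1 sites on X and at ribosomal protein and snoRNA promoters, of chance and of extra copies around fos-1, were chosen only after the result was seen. Sequences other than the AP-1 motif also stood out at IDR summits. Of 2080 hexamers, 142 passed against the flanks, 98 of them higher. GACGCA was in 52 of 248 summit windows and 12 of 496 flanks (adjusted p = 4.02e-13, Fisher's exact test), and GAGAGA in 94 and 61 (adjusted p = 3.76e-12, Fisher's exact test). The hexamer GAGTCA, a part of the AP-1 motif, was in 37 and 32 (adjusted p = 0.00984, Fisher's exact test). Its odds ratio of 2.54 was below the 10.7 of GACGCA. GACGCA was in 23.8% of promoter peaks and 18% of the others (Fisher's exact p = 0.279). Mean GC content was 41.0% at summits, 37.7% in the flanks and 34.2% in the lower-ranked part of the list. Over the whole pooled list, the 106 regions with an AP-1 motif had a mean rank of 1429 against 1764 for all regions (permutation p = 5.90e-04).

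Among the highest signals, where X-linked peaks were concentrated, 7 of the 11 X-linked peaks of the top 20 had the MEX consensus TCGCGCAGGGAG, a motif of sites where the dosage compensation complex is recruited to X, which was present with up to 2 mismatches in 25.5% of the 55 X-linked windows and 1.04% of the 193 autosomal ones (Fisher's exact p = 1.39e-08). Without MEX-bearing peaks the median signal on X minus that on the autosomes was −1.08 (bootstrap 95% interval −4.29 to 5.05). This is a drop of 6.86 (95% interval 1.27 to 15.7) from the 5.78 over all peaks, whose own interval includes 0. The MEX-bearing peaks on X were already seen to have higher signals, so the drop restates that split. By itself it does not decide about a rise over the whole of X. No higher median on X was seen among the peaks without MEX, while a smaller rise stays open. For the place in the top 20 a rise over the whole of X cannot be told apart from chance or other causes with so few peaks: without MEX-bearing peaks, 4 of 41 X-linked and 9 of 191 autosomal peaks were there (odds ratio 2.19, 95% interval 0.465 to 8.33, Fisher's exact p = 0.253), and the X share did not pass against the lower-ranked regions (22.2% against 17.1%, Fisher's exact p = 0.0619). The AP-1 motif was in 7.27% of X-linked and 8.29% of autosomal windows, a comparison chosen before its result was seen that decided nothing (odds ratio 0.868, 95% interval 0.202 to 2.85, Fisher's exact p = 1.00). Its upper 95% limit of 17.6% on X means that AP-1 consensus sites do not account for most X-linked peaks. Most autosomal windows lacked the motif too, so this limit says nothing particular to X. A candidate explanation is that MEX-bearing sites draw signal in this assay, and whether through FOS-1 or regardless of the tagged protein was not tested, because no ChIP of another protein was used here.

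Ribosomal protein and snoRNA promoters carried more peaks than other genes. Without the peaks at ribosomal protein promoters, the snoRNA odds ratio fell from 9.20 (16 genes) to 5.43 (9 genes, Fisher's exact p = 7.48e-05). Promoters shared with ribosomal protein genes thus carried part of the excess. Against all other genes with a position, the rest argues against these as the whole cause. Against protein-coding genes the odds ratio with all peaks was 5.97, and the removal was not run in that comparison. Promoters shared with other protein-coding genes, as for C06A1.9 at the cdc-48.1 peak, were not removed, so their part stays open. Ribosomal protein genes, rpl-7A included, were 5.59% of the genes at IDR peaks and 0.427% of those at the lower-ranked part of the list (Fisher's exact p = 2.96e-05), which argues against any promoter being as likely to be listed. The AP-1 motif was in 0 of the 18 peaks (upper 95% limit 18.5%) and 8.70% of the other 230, a difference that did not pass (Fisher's exact p = 0.375). AP-1 consensus sites near the summit therefore do not account for most of these peaks. That holds for the other peaks too, so it sets nothing apart at these promoters. Weaker sites and indirect binding were not tested. Whether the peaks follow the transcription of these genes was not tested.

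A stretch around fos-1 had no region in either replicate list. It runs from V 5978329 to 6030143, 51815 bp with 8 whole protein-coding genes, against a genome-wide median gap between neighbouring summits of 2161 bp in replicate 1 and 2156 bp in replicate 2. Only 0.421% of protein-coding genes lie in stretches as long in both lists, which argues against chance, although 6 loci were looked at; its soft-masked share of 29.1% is at the 34th percentile of 2000 random stretches, which argues against repeats. Extra copies of the region in the strain could raise the background there, but 3 other stretches on V are as long in both lists, and without read coverage this explanation cannot be told apart from others. No biological explanation was tested.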
